A study of Solanum lycopersicum with 6 samples.

How the data were processed

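RNA was measured by sequencing in exocarp, the outer fruit layer (epidermis with its cuticle and the cells under it), of wild-type (WT) tomato and of a knockout of the NAC transcription factor SlNOR-like1 (nor-like1), both at the stage labelled MG. Each genotype had 3 libraries, made from Trizol-extracted total RNA with MGI library protocols, per the labels' protocols. Nothing in the labels says whether the 3 libraries of a genotype came from separate plants or fruits, so p-values measure only the spread between these libraries, which may be technical.

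The authors deposited 1 table per library with RSEM expected counts per gene, which need not be whole numbers, and FPKM, per the file headers. HISAT2, StringTie, Bowtie2 and RSEM are named in the submitters' processing notes, without versions or the role of each; the genome build and the annotation are not given in the sources used here, and neither is whether counting used strand. Each table lists only genes above 0, and a gene listed in another library was set to 0. Of 21708 genes listed in any library, 17468 were listed in all 6. Expected counts can divide reads between near-identical paralogs, so single members of families such as the lipid-transfer proteins, multicystatins, heat shock proteins and chlorophyll-binding proteins are uncertain. Of the genes tested, 27 had the same expected counts in all 6 libraries as at least 1 other and held 10 distinct sets of counts; each was tested as its own gene. Gene descriptions, best protein hits and annotation terms came from the same tables. The RefSeq accession of the best protein hit was found in the reference table of assembly SLM_r2.1 for 15869 genes; that assembly may differ from the authors' build, so no coordinates are given.

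The authors also deposited a DESeq2 comparison, with a log2 fold change, a p-value and an adjusted p-value per gene, per the file headers. Its 2 group expression columns are the authors' values on a scale not given; for 11100 genes above 100 in both columns of the authors' deposited table, the log2 ratio of those columns lay a median of -1.24 (quartiles -1.26 and -1.22) from its own fold change column. The levels were therefore not used, and the fold changes were only set beside the values computed here.

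Total expected counts were 17578533, 11459875 and 16203692 in WT replicates 1 to 3 and 11023036, 10000909 and 8503210 in nor-like1 replicates 1 to 3. A floor of 3 counts corresponds to between 0.171 CPM (WT replicate 1) and 0.353 CPM (nor-like1 replicate 3); such limits cover counting error only. No pair of libraries of 1 genotype agreed within sampling noise, with a chi-square per gene between 10.5 and 47.

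Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 under R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood fit, quasi-likelihood F test, genotype as the only term), which left 16380 genes. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Every adjusted p of a single gene comes from this test unless another tool is named. Log2 fold changes are nor-like1 over WT, and their standard error (SE) was taken as the absolute fold change over the square root of the F statistic. CPM, counts scaled by library size and TMM factor, are given as mean ± SD over 3 libraries.

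Before the data were examined, 20 gene lists were fixed by patterns on product descriptions and by gene identifiers. The patterns were then matched to the best protein hit as well as to the product description, which the fixed rule did not name. Some members, such as CYP86A1 and ECERIFERUM 26-like, entered through the best protein hit alone. The lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, adjusted over the 20 lists. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list changed more than the other genes, and fry whether it changed at all. The patterns also take some members with other functions. The cutin list holds CD2, a regulator, and a pair of lysophosphatidate acyltransferases, the transport list glycolipid transfer proteins, and the wax list peptidylprolyl isomerases. The seed list takes lipid-transfer proteins described by a seed storage domain, and hydroxyproline-rich LEA proteins. The plastid fatty acid list holds an omega-6 desaturase whose best protein hit is an endoplasmic reticulum isozyme. Annotation terms (GO and pathways) with 10 to 500 tested genes were tested with the one-sided Fisher's exact test for higher and lower genes separately. The 687 terms were adjusted together over both directions, against the 12243 tested genes that carry a term.

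The rule for genes to be named, and the alternatives below except where said otherwise, were fixed at the same time. They are SlNOR-like1 and NOR; the 8 largest rises and 8 largest falls among called, described genes with a mean of at least 5 CPM and groups that do not overlap; and the called members with the smallest adjusted p, 4 for each cuticle and ripening list and 2 for each other list. Some genes outside this rule are named too, and the text says where. Some genes that the rule takes are not reported here. RIN, SHN3 and GAME9 were among the listed identifiers and are not analysed here.

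Counts of 16380 genes were simulated with the means, library sizes and dispersions of these libraries. Of these, 200 genes were changed, drawn only from genes with a mean of at least 1 CPM. There edgeR recovered 94% of genes raised 4-fold and 58% of genes raised 2-fold, and 86% and 46% of genes lowered to 0.25 and 0.5. Of its calls 10.7% were genes that had not been changed, against 23.1% for DESeq2 and 8.2% for limma in the same simulation. These shares hold for that simulated setting of nor-like1 against WT only. Far more genes were called in the real comparison (3585), and recovery below 1 CPM was not simulated.

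The alternatives were DESeq2 1.42.0, RLE or upper-quartile factors, and no low-count filter or at least 1 CPM in 3 libraries. Limma was run on log2(FPKM + 1) and on log2(FPKM + 0.1) with a filter of FPKM 1 in 3 libraries. On log2(FPKM + 1) it was also run without that filter. Further alternatives were the replicate number as a block, each library left out in turn, glmTreat and other set tests. Other calls were used for the enrichment and for the comparison with the deposited table. Thinned counts, a shorter cutin list and shorter photosynthesis lists were added after seeing the data.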

Results

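Transcript levels were compared between the exocarp of WT tomato and of SlNOR-like1 knockout fruit, to ask which genes of cuticle metabolism change when this transcription factor is lost. The 3 WT libraries held between 11459875 and 17578533 expected counts and the 3 nor-like1 libraries between 8503210 and 11023036, so each WT library was deeper than each nor-like1 library.

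The SlNOR-like1 transcript itself (Solyc07g063420.3) was lower in every nor-like1 library than in any WT library. It measured 129.8, 114.3 and 120.8 CPM in WT replicates 1 to 3 and 24.52, 16.93 and 18.05 CPM in nor-like1 replicates 1 to 3. The means were 121.6 ± 7.78 and 19.83 ± 4.1 CPM (SD, n = 3 each). The log2 fold change was -2.61 (SE 0.162; edgeR quasi-likelihood adjusted p = 0.000532), so that the mutant kept 0.163 of the WT level. NOR (Solyc10g006880.3), the related NAC factor that controls ripening, gave a log2 fold change of 0.18 (SE 0.554) and an adjusted p of 0.837. Its level was 199.3 CPM in nor-like1 replicate 1 against 51.85 and 53.31 CPM in the other two, and without nor-like1 replicate 1 its log2 fold change was -0.77 with an adjusted p of 0.0305.

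**Figure D1:**
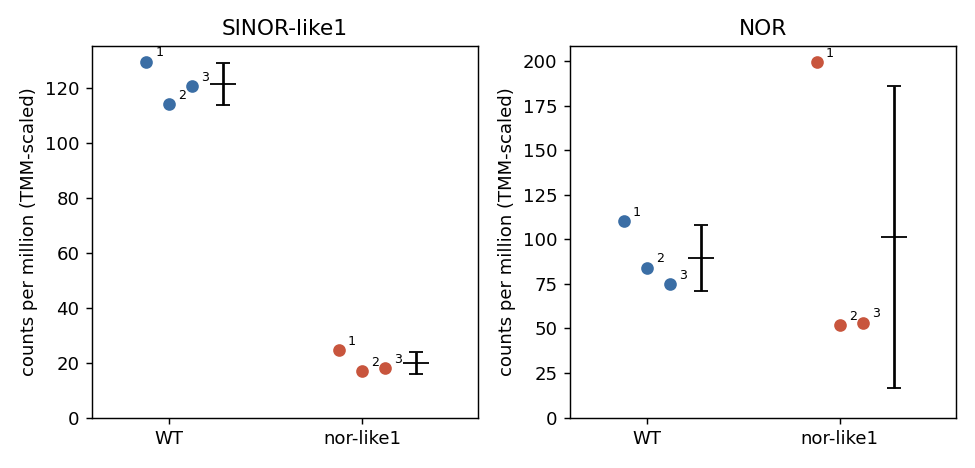
CPM of SlNOR-like1 (left) and NOR (right) in each library (points, with the replicate number) and the mean with SD of each genotype (bars, n = 3). SlNOR-like1 lies between 114.3 and 129.8 CPM in WT and between 16.93 and 24.52 CPM in nor-like1, while NOR in nor-like1 replicate 1 stands at 199.3 CPM.

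Loss of SlNOR-like1 went with a broad change of the exocarp transcriptome. The largest rises included PR1, a secreted pathogenesis-related protein, and multicystatins, which inhibit cysteine proteases. The largest falls included several small heat shock proteins, which protect other proteins from aggregation. Of 16380 genes tested, 1713 were higher and 1872 lower in nor-like1 (3585 in all), and 897 and 473 of these changed at least 2-fold (1370 in all). The 2 genotypes did not overlap at 42.9% of tested genes, where chance gives 10%. The counts depended on single libraries: 1502 genes were called without WT replicate 1, 1139 (714 at least 2-fold) without WT replicate 2, 1406 (803) without nor-like1 replicate 2 and 1651 without nor-like1 replicate 3. Without WT replicate 3, which lay nearer to nor-like1 than the other WT libraries on the first principal component (-23.2 against -74.6 and -61.8, nor-like1 between 41 and 60.8), 4742 were called.

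Among the 8 largest rises of described genes with a mean of at least 5 CPM, PR1 (Solyc01g106620.2) went from 0.0995 ± 0.0923 CPM in WT to 43.19 ± 5.05 CPM in nor-like1 (SD, n = 3 each; adjusted p = 0.000219). A multicystatin (Solyc06g073587.1) went from 16.71 ± 15.3 to 1970 ± 913 CPM (adjusted p = 0.0115), and a further one (Solyc06g150133.1) rose by a log2 fold change of 6.98 (SE 1.264; adjusted p = 0.015). Without WT replicate 2 their adjusted p were 0.0584 and 0.0693, and without WT replicate 3 their log2 fold changes were 7.83 and 9.02; the latter gene gave 6.33 without nor-like1 replicate 3. A tropinone reductase homolog (Solyc06g083470.5), polyphenol oxidase F (Solyc08g074630.2), which oxidises phenolics, and extensin-2 (Solyc09g098510.4), a cell wall glycoprotein, rose by log2 fold changes of 8.81 (SE 0.605), 8.76 (SE 1.054) and 6.67 (SE 0.369). The WT libraries together held only 5, 8 and 7 counts of them, so the sizes are uncertain. Across all alternatives the log2 fold changes ranged from 5.05 to 9.13, 5.12 to 9.32 and 2.31 to 7.48. Such ranges, here and below, include limma on log2(FPKM + 1). There the added 1 shrinks the change of a gene near 0 in a genotype, so not all values are on the edgeR scale. Polyphenol oxidase F gave 8.09 without WT replicate 1 and 7.75 without nor-like1 replicate 3. A histidine decarboxylase homolog (Solyc08g006750.4) had 3 counts over the WT libraries and 515 over the nor-like1 libraries, a depth-scaled ratio of 263 with a counting interval of 89.5 to 1280. The allene oxide synthase CYP74C3 (Solyc10g007960.1), of oxylipin metabolism, rose by a log2 fold change of 8.24 (SE 1.496; adjusted p = 0.0152), with an adjusted p of 0.0541 without WT replicate 1 and 0.0785 without WT replicate 2. Its log2 fold change ranged from 6.63 without nor-like1 replicate 1 over 7.59 and 7.64 without WT replicates 1 and 3 to 11.59 without WT replicate 2. The WT libraries together held 4 counts of it, and across all alternatives the lowest log2 fold change was 3.79.

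Among the 8 largest falls under the same limits, the SEC3A-like exocyst subunit (Solyc07g025170.3), part of the secretory machinery, went from 21.53 ± 2.91 to 0.1795 ± 0.178 CPM (SD, n = 3 each; adjusted p = 0.000532), a log2 fold change of -6.91 that was -7.7 without nor-like1 replicate 3. A glutathione S-transferase (Solyc07g056510.3) went from 49.86 ± 32.5 to 0.243 ± 0.421 CPM (adjusted p = 0.00705); its log2 fold change of -7.49 was -6.9 without WT replicate 1 and -12.31 without nor-like1 replicate 1. Small heat shock proteins Solyc03g082420.3 and Solyc05g014280.4 fell to 0.0492 and 0.0587 of WT (adjusted p = 0.00848 and 0.00575), and the class IV heat shock protein Solyc03g113930.3 to 0.0578 (adjusted p = 0.0236, above 0.05 when any 1 library other than WT replicate 3 was left out, between 0.0532 and 0.0804; its log2 fold change of -4.11 was -3.46 without WT replicate 1 and -4.87 without nor-like1 replicate 2). A ribosomal protein L4 (Solyc10g047150.3), a beta-glucosidase 44-like protein (Solyc12g040640.2) and a photosystem II 5 kDa protein (Solyc01g008510.3) fell to 0.0253, 0.0664 and 0.0722 of WT. The nor-like1 libraries together held 5 counts of the exocyst subunit, 8 of the glutathione S-transferase and 20 of ribosomal protein L4. Across all alternatives their log2 fold changes ranged from -7.7 to -2.83, -12.31 to -5.25 and -5.71 to -1.63. The photosystem protein's log2 fold change of -3.79 was -4.81 without nor-like1 replicate 1. The glutathione S-transferase, the ribosomal protein L4 and the small heat shock proteins were lower in WT replicate 3 than in the other WT libraries: ribosomal protein L4 measured 9.662 CPM there, against 36.32 and 35.4 CPM.

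Genes for the cuticle, the cutin and wax layer that seals the fruit, included members that rose and members that fell. The wax synthesis list was higher in nor-like1 (camera adjusted p = 1.32e-05, and adjusted p = 0.212 with an estimated correlation). List calls here and below rest on camera with the preset correlation, and 0 lists held with an estimated one. Groupings of the 6 libraries that mix the genotypes also gave up to 9 called lists, as many as the real grouping. The cutin list as a whole was not called and had 6 members higher and 6 lower. Of 39 wax synthesis genes tested, 18 rose, 1 fell and 20 were not called (20 up and 1 down adjusted over the list alone), with a median log2 fold change of 0.66. The list's mean level in WT replicate 3 lay 0.28 above the other WT libraries on the log2 scale, which is 29.1% of the difference between genotypes. 3-ketoacyl-CoA synthase 1 (Solyc10g009240.3), which elongates fatty acids, rose 12.5-fold (log2 SE 0.216) and an ECERIFERUM 1-like gene of alkane formation (Solyc01g088400.4) 13.7-fold (log2 SE 0.26). The abundant ECERIFERUM 3 (Solyc03g117800.4) went from 715.3 ± 151 to 2103 ± 250 CPM and ECERIFERUM 26-like (Solyc09g092270.3) from 112.4 ± 5.96 to 270.2 ± 60.6 CPM (SD, n = 3 each). The 1 member that fell, named after its value was seen, was a WSD1-like wax ester acyltransferase (Solyc01g107900.3; log2 fold change -0.4, adjusted p = 0.0283). Its adjusted p was between 0.0551 and 0.118 when any 1 library other than WT replicate 3 was left out.

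Of 35 cutin synthesis genes tested, 6 rose, 6 fell and 23 were not called (8 up and 6 down adjusted over the list alone), with a camera adjusted p of 0.407. WT replicate 3 lay 0.36 above the other WT libraries for the mean of this list on the log2 scale, against a difference of 0.29 between genotypes. The cytochrome P450 77A1 gene (Solyc11g007540.2), a fatty acid hydroxylase, fell by 1.55 on the log2 scale (SE 0.29; adjusted p = 0.0147, 0.0612 without nor-like1 replicate 2). Bifunctional epoxide hydrolase 2 (Solyc12g099430.2) went from 230.3 ± 4.16 to 108.2 ± 31.8 CPM (SD, n = 3 each; adjusted p = 0.0153, 0.065 without WT replicate 2 and 0.0549 without nor-like1 replicate 3). GPAT6 (Solyc09g014350.3), the acyltransferase of cutin monomer synthesis, and CYP86A69 (Solyc08g081220.1), an omega-hydroxylase of cutin acids, were named after their values were seen. They fell by 1.30 (SE 0.298; adjusted p = 0.0279) and 0.78 (SE 0.175; adjusted p = 0.0226) on the log2 scale. For GPAT6 the adjusted p was 0.0671 without WT replicate 1, 0.0732 without WT replicate 2 and 0.0849 without nor-like1 replicate 3. For CYP86A69 it was 0.0583 without WT replicate 2 and 0.0735 without nor-like1 replicate 2. CYP86A1 (Solyc06g076800.3), known from suberin synthesis, reached 2.333 ± 0.514 CPM from 0.081 ± 0.14 CPM (adjusted p = 0.0103). Its log2 fold change of 4.58 was 3.96 without WT replicate 1 and 7.77 without WT replicate 3. The omega-hydroxypalmitate O-feruloyl transferase (Solyc03g097500.3), also of suberin synthesis, reached 2.352 ± 0.395 from 0.7309 ± 0.178 CPM (adjusted p = 0.0155, 0.0655 without WT replicate 2 and 0.0524 without nor-like1 replicate 3).

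The other cutin list members called were named after their values were seen. Among the higher ones, the cytochrome P450 86A8-like gene (Solyc04g082380.4) went from 2.646 ± 0.803 to 6.226 ± 0.617 CPM (SD, n = 3 each; adjusted p = 0.0197, 0.0651 without WT replicate 1, 0.0618 without WT replicate 2 and 0.075 without nor-like1 replicate 2). Long chain acyl-CoA synthetase 5 (Solyc01g095750.3) reached 1.68 ± 0.566 from 0.199 ± 0.181 CPM (adjusted p = 0.0278). It was not called without WT replicate 2 (0.0664) or nor-like1 replicates 1, 2 and 3 (0.0588, 0.0629 and 0.084), and its log2 fold change of 3.13 was 2.48 without WT replicate 1 and 3.71 without WT replicate 2. An alpha/beta-hydrolase (Solyc01g099910.5) reached 2.188 ± 0.369 from 0.3509 ± 0.383 CPM (adjusted p = 0.0312; 0.0943 and 0.0918 without WT replicates 1 and 2, 0.0886 and 0.0962 without nor-like1 replicates 2 and 3). Its log2 fold change of 2.53 was 3.87 without WT replicate 3. An epoxide hydrolase (Solyc02g078570.3) went from 31.72 ± 3.59 to 58.56 ± 17.9 CPM (adjusted p = 0.0418). When 1 library was left out it was called only without nor-like1 replicate 1 (0.00473) and otherwise lay between 0.0538 and 0.134. Among the lower ones, a further epoxide hydrolase (Solyc05g054350.3) went from 669.6 ± 58.1 to 398.2 ± 83.4 CPM (adjusted p = 0.0267; 0.0671 and 0.102 without WT replicates 1 and 2, 0.0696 and 0.0508 without nor-like1 replicates 2 and 3). An HXXXD-type acyltransferase (Solyc11g008630.3) had a log2 fold change of -0.56 (adjusted p = 0.0239, 0.0808 without WT replicate 2 and 0.0855 without nor-like1 replicate 2).

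GDSL lipases, the family that includes cutin synthase, were higher as a list: of 40 tested, 11 rose, 1 fell and 28 were not called (12 up and 1 down adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.212 with an estimated correlation). WT replicate 3 lay 0.37 above the other WT libraries for the mean of this list on the log2 scale, which is 49% of the difference between genotypes. Solyc07g049440.3 went from 55.6 ± 10.8 to 331.2 ± 46.9 CPM and Solyc02g071700.3 from 5.452 ± 5.25 to 309.7 ± 63.5 CPM (SD, n = 3 each), a log2 fold change of 5.81 that was 7.02 without WT replicate 3. The 1 member that fell, named after its value was seen, was Solyc01g099020.3 (log2 fold change -1.84, adjusted p = 0.0181). It was not called without WT replicate 1 (0.0582), WT replicate 2 (0.0692) or nor-like1 replicate 2 (0.0742). Cutin synthase (Solyc11g006250.2), named after its value was seen, had a log2 fold change of 0.96 (SE 0.279) with an adjusted p of 0.0529, which was 0.00746 without WT replicate 3 and 0.0449 without nor-like1 replicate 1. Cuticle lipid transport had 14 members higher, 5 lower and 21 not called of 40 (the same counts adjusted over the list alone). Its camera adjusted p was 0.0405, and adjusted p = 0.212 with an estimated correlation; the call was lost with DESeq2 (0.0507), upper-quartile factors (0.0501) and the 1 CPM filter (0.0551). For this list WT replicate 3 lay 0.33 above the other WT libraries, 63% of the difference between genotypes. Lipid-transfer protein Solyc10g075100.2, already abundant, went from 1889 ± 129 to 5304 ± 535 CPM, Solyc10g075110.2 rose 10.5-fold, and the lipid exporter ABCG11-like (Solyc03g019760.4) rose 2.23-fold (log2 SE 0.12).

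The cuticle regulators were not called as a list (11 tested, 3 higher, 1 lower and 7 not called, the same adjusted over the list alone; camera adjusted p = 0.659). The HDG1-like homeodomain-leucine zipper factor (Solyc06g035940.3), of a family that acts in the epidermis, went from 247.7 ± 20.2 to 27.63 ± 21.4 CPM (SD, n = 3 each; adjusted p = 0.0125, 0.0527 without nor-like1 replicate 2). Its log2 fold change of -3.17 was -4.01 without nor-like1 replicate 3. MYB31 (Solyc03g116100.3) rose 2.83-fold (adjusted p = 0.022; 0.0872 without WT replicate 2, 0.0778 without nor-like1 replicate 2 and 0.0591 without nor-like1 replicate 3). MERISTEM L1-like (Solyc03g031760.5) and HDG11-like (Solyc06g072310.3) gave 2.05-fold and 1.79-fold with adjusted p of 0.0235 and 0.0377. MERISTEM L1-like was not called without WT replicate 1 (0.0724), WT replicate 2 (0.0898), nor-like1 replicate 2 (0.0826) or nor-like1 replicate 3 (0.075), nor with limma without a filter (0.0599). HDG11-like was not called without any 1 library except WT replicate 3 (0.0555 to 0.127). It was also not called with DESeq2 (0.0841), with limma (0.0566 to 0.0711), with the replicate block (0.0827), with counts thinned to the smallest library (0.0804) or without a low-count filter (0.0525).

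**Figure D2:**
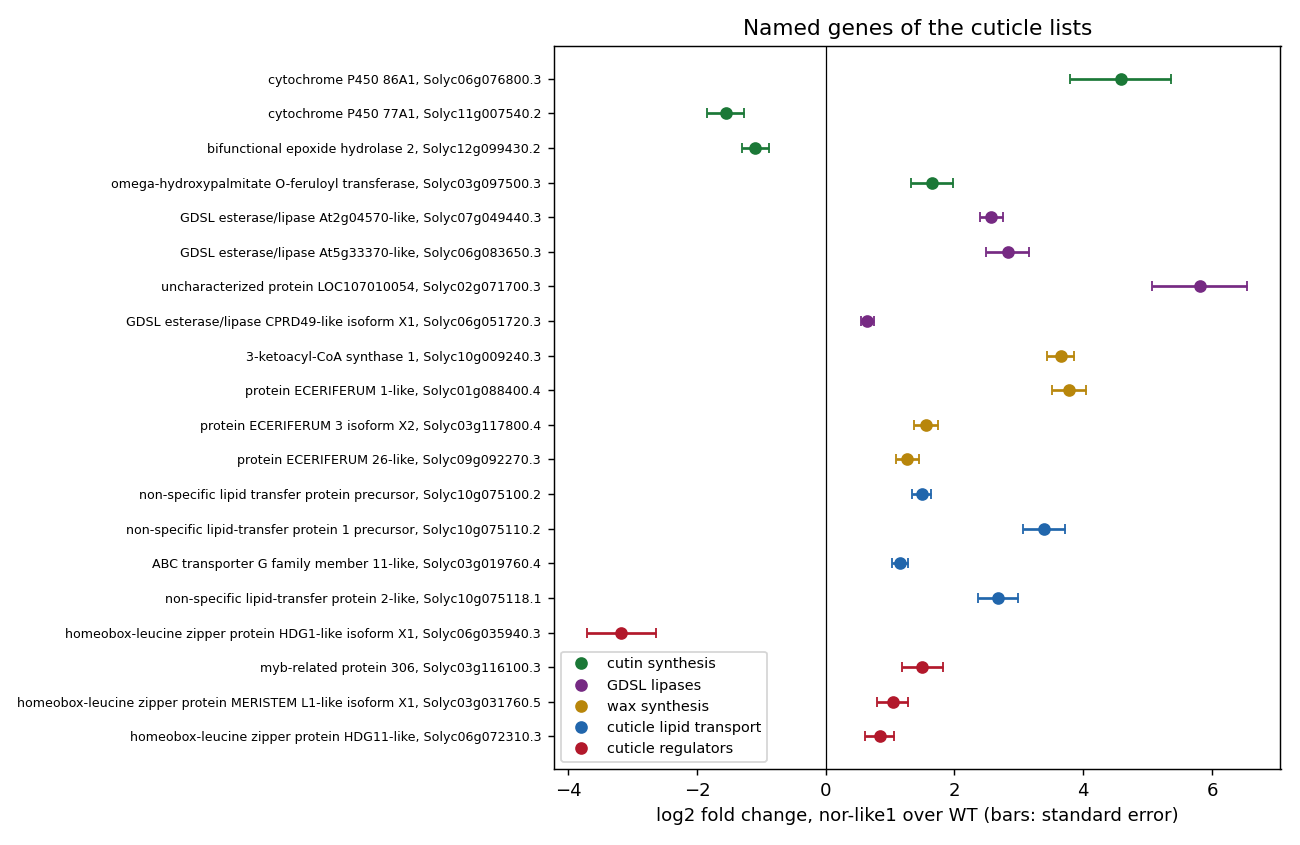
Log2 fold change (nor-like1 over WT, horizontal axis) with its standard error for the 20 named genes of the 5 cuticle lists, from 3 libraries per genotype. The wax and transport genes plotted lie to the right of 0, and the HDG1-like factor is lowest at -3.17. Not plotted are the 5 transport members and 1 wax member that were called lower.

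Among phenylpropanoid and steroidal glycoalkaloid genes, several rose. Of 64 phenylpropanoid and flavonoid genes, 27 rose, 6 fell and 31 were not called (30 up and 8 down adjusted over the list alone), with a camera adjusted p of 1.32e-05, and adjusted p = 0.212 with an estimated correlation. Caffeoyl-CoA O-methyltransferase (Solyc10g050160.2) of lignin synthesis rose 31-fold, and 4-coumarate-CoA ligase (Solyc03g117870.3) went from 83.22 ± 7.75 to 310.1 ± 62.4 CPM (SD, n = 3 each). The mean of this list in WT replicate 3 lay 0.42 above the other WT libraries on the log2 scale, which is 41.2% of the difference between genotypes. Of 5 glycoalkaloid genes, 2 rose and 3 were not called (the same adjusted over the list alone; camera adjusted p = 0.0405, and adjusted p = 0.364 with an estimated correlation): GAME4 (Solyc12g006460.2, whose best protein hit is named ent-kaurenoic acid oxidase) 9.85-fold and a delta(24)-sterol reductase (Solyc02g069490.4) 8.57-fold, the latter a log2 fold change of 3.10 that was 2.51 without nor-like1 replicate 3. That list's call was lost without nor-like1 replicate 3 (0.0701), with DESeq2 (0.0533), without a low-count filter (0.0761) and with limma without a filter (0.0923). Plastid fatty acid synthesis was not called (42 tested, 5 higher, 1 lower and 36 not called, 5 and 0 adjusted over the list alone; camera adjusted p = 0.0525, and 0.0377 without WT replicate 2), and WT replicate 3 lay 0.48 above the other WT libraries, against 0.43 between genotypes. Its members with the smallest adjusted p were an omega-6 desaturase (Solyc01g006430.3, 2.17-fold) and biotin carboxylase 1 (Solyc01g008330.5, 1.6-fold). The best protein hit of the desaturase is an endoplasmic reticulum isozyme, so it is not a plastid gene by that name.

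As lists, transcripts of defence proteins were higher and those of heat shock proteins lower in camera with the preset correlation only. About as many members were not called as called. Of 92 defence genes, 37 rose, 4 fell and 51 were not called (43 up and 5 down adjusted over the list alone), with a camera adjusted p of 4.14e-10, and adjusted p = 0.214 with an estimated correlation. Beside PR1 (Solyc01g106620.2), PR4b (Solyc01g097280.3) rose 21.8-fold. Of 68 heat shock genes, 33 fell, 1 rose and 34 were not called (37 down and 3 up adjusted over the list alone), with a camera adjusted p of 1.97e-08, and adjusted p = 0.234 with an estimated correlation. The class I protein Solyc06g076520.1 went from 229.5 ± 45.5 to 47.19 ± 8.61 CPM and the peroxisomal protein Solyc04g014480.3 from 299.8 ± 78.2 to 65.43 ± 5.77 CPM (SD, n = 3 each). The 1 member that rose, named after its value was seen, was heat shock transcription factor 8 (Solyc04g016000.3), at 12.46 ± 2.47 against 0.2836 ± 0.491 CPM (adjusted p = 0.0116). Its log2 fold change of 5.3 was 4.65 without WT replicate 1 and 10.18 without WT replicate 3. Both lists also moved within WT: replicate 3 lay 0.66 above the other WT libraries for defence and -0.37 from them for heat shock on the log2 scale, which is 39.9% and 34.6% of the difference between genotypes.

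The photosynthesis list was lower. Of 92 entries, 38 fell, 2 rose and 52 were not called (48 down and 4 up adjusted over the list alone), with a camera adjusted p of 3.89e-06, and adjusted p = 0.212 with an estimated correlation. None of the 38 was among the 16 entries with a Solyc00g identifier, whose products, such as the D1 protein of photosystem II, are mostly known as plastid-encoded. Of these, 0 were called and 15 had a log2 fold change above 0 (0.37 to 0.82). Those 15 shared their counts in all 6 libraries with at least 1 other entry, so the 16 hold only 6 distinct sets of counts. With identical entries counted once, 82 remained (38 lower, 2 higher, 42 not called; camera adjusted p = 1.03e-08, and adjusted p = 0.212 with an estimated correlation). Rubisco activase (Solyc09g011080.3) went from 191.7 ± 30.3 to 33.93 ± 6.38 CPM and a PsbP-domain protein (Solyc04g064670.3) from 41.55 ± 1.45 to 18.13 ± 2.41 CPM (SD, n = 3 each). The 2 members that rose, named after their values were seen, were chlorophyll a-b binding proteins, Solyc02g070940.1 (log2 fold change 1.42, adjusted p = 0.0125) and Solyc03g115900.5 (1.2, adjusted p = 0.047). The latter was called only without nor-like1 replicate 1 (0.00511) when 1 library was left out, and was otherwise between 0.0656 and 0.143. WT replicate 3 stood with the other WT libraries for this list (-0.006, WT replicates 1 and 2 at 0.02 and -0.014).

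**Figure D3:**
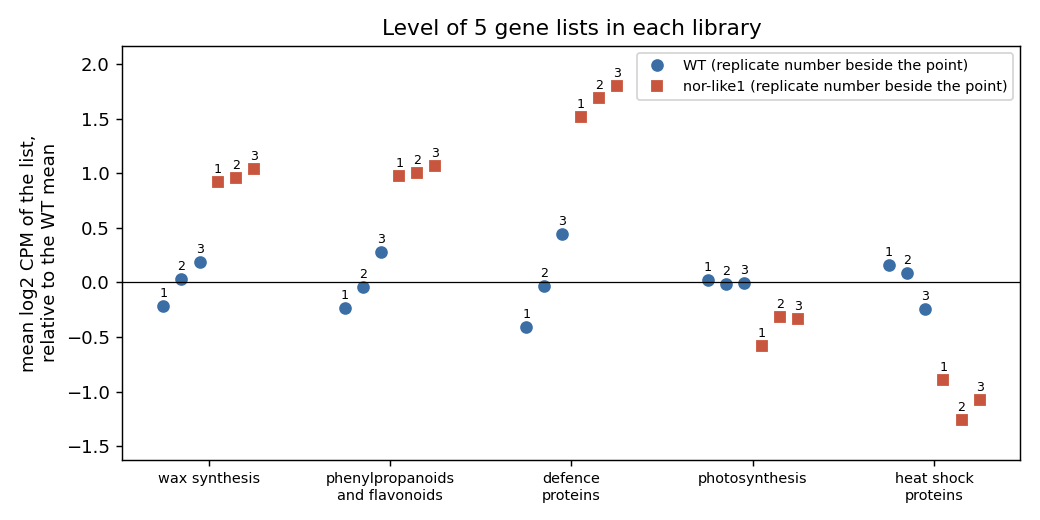
Mean log2 CPM of 5 gene lists in each library, relative to the mean of the WT libraries (circles WT, squares nor-like1, with replicate numbers). Defence proteins lie between 1.516 and 1.799 in nor-like1 and at 0.443 in WT replicate 3, and photosynthesis between -0.584 and -0.321 in nor-like1.

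Ripening genes did not move one way. Of 44 ethylene and ripening regulators, 2 rose, 7 fell and 35 were not called (2 up and 6 down adjusted over the list alone), with a camera adjusted p of 0.929; the median log2 fold change was -0.01 and the mean 0.263, so they differed in sign. The ripening regulator CNR (Solyc02g077920.4) went from 427 ± 76.7 to 189 ± 18.6 CPM (SD, n = 3 each), and the ACC oxidase homolog Solyc04g007980.3 fell to 0.568 of WT (adjusted p = 0.0112, 0.0508 without WT replicate 2). That name is of its best protein hit, as for the homolog Solyc09g089680.4. The product descriptions give only an oxygenase superfamily, so a part of either gene in ethylene synthesis is not shown here. Solyc09g089680.4 reached 2.149 ± 1.03 CPM from 0.0876 ± 0.0872 CPM. Its log2 fold change of 4.46 was 5.51 without WT replicate 1 and 3.86 without WT replicate 3. The list's direction in camera turned upward without WT replicate 3 (0.855) and without nor-like1 replicate 3 (0.689). Of 28 carotenoid genes, 7 fell, 1 rose and 20 were not called (7 and 2 adjusted over the list alone; camera adjusted p = 0.0671, 0.0418 without WT replicate 2 and 0.0461 without nor-like1 replicate 1). Zeaxanthin epoxidase (Solyc02g090890.4) and beta-carotene hydroxylase (Solyc06g036260.3) fell to 0.385 and 0.387 of WT, and the chromoplast lycopene beta-cyclase (Solyc06g074240.3) rose 5.23-fold from a low level. Phytoene synthase 2 (Solyc02g081330.4) gave 0.703 of WT (adjusted p = 0.0158; 0.0614 and 0.0501 without WT replicates 1 and 2, 0.0563 and 0.0564 without nor-like1 replicates 2 and 3).

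Of 118 cell wall remodelling genes, 30 rose, 17 fell and 71 were not called (30 and 19 adjusted over the list alone; camera adjusted p = 0.0525). Xyloglucan endotransglucosylase/hydrolase 32 (Solyc09g008320.5) and cellulose synthase-like G3 (Solyc12g014430.2) rose 3.67-fold and 3.17-fold. Pectinesterase 29 (Solyc12g098340.2) and a polygalacturonase (Solyc05g049980.3), both pectin-modifying, fell to 0.173 and 0.213 of WT. WT replicate 3 lay 0.19 above the other WT libraries for this list on the log2 scale, 54.5% of the difference between genotypes. The list's adjusted p was 0.04 without WT replicate 1, 0.0377 without WT replicate 2, 0.0451 without WT replicate 3 and 0.00724 without nor-like1 replicate 1.

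Lists named for other tissues or states were also counted. The seed list also takes lipid-transfer proteins described by a seed storage domain, so its counts do not stand for seed tissue alone. Cell division genes were higher (148 tested, 28 rose, 6 fell, 114 not called; 31 and 7 adjusted over the list alone; camera adjusted p = 0.00264, adjusted p = 0.395 with an estimated correlation, and 0.0547 without nor-like1 replicate 1). The replication licensing factors MCM5 (Solyc07g005020.3) and MCM4 (Solyc01g110130.3) rose 5.11-fold and 5.07-fold. Of 28 vascular genes, 7 rose, 2 fell and 19 were not called (9 and 3 adjusted over the list alone; camera adjusted p = 0.0529). It was 0.0466, 0.0418 and 0.0459 without WT replicates 1, 2 and 3 and 0.0104 without nor-like1 replicate 1. WT replicate 3 lay 0.25 above the other WT libraries for the vascular list on the log2 scale, 38% of the difference between genotypes. Higher members were a xylem cysteine proteinase (Solyc02g076730.4) from 11.84 ± 0.49 to 108.6 ± 27.9 CPM and laccase-3-like (Solyc06g082240.2) from 0.6825 ± 0.779 to 48.68 ± 20.1 CPM (SD, n = 3 each); the laccase's log2 fold change of 6.05 was 7.57 without WT replicate 3. Of 48 seed-type genes, 5 rose, 9 fell and 34 were not called (6 and 10 adjusted over the list alone; camera adjusted p = 0.892, with the direction turned without WT replicate 2 at 0.855 and without nor-like1 replicate 2 at 0.981), and of 7 trichome genes 2 rose and 5 were not called (3 and 0 adjusted over the list alone; camera adjusted p = 0.184). The trichome members were monoterpene synthase 1 (Solyc01g105890.3; log2 fold change 4.26, adjusted p = 0.0377) and a sesquiterpene synthase (Solyc12g006570.2; 1.04, adjusted p = 0.0428). The former was called with 1 library left out only without WT replicate 3 (8.16 on the log2 scale, adjusted p = 0.00232) and otherwise lay between 0.0522 and 0.12, with 3.64 on the log2 scale without WT replicate 1. The former was also not called with DESeq2 (0.0649) or without a low-count filter (0.0868). The latter was not called without any 1 of the 6 libraries (0.0585 to 0.127), nor with DESeq2 (0.06), limma (0.0668 to 0.0733), the replicate block (0.0882) or thinned counts (0.0515).

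Among jasmonate, ABA and auxin genes, 15 rose, 14 fell and 137 were not called of 166 (11 and 10 adjusted over the list alone; camera adjusted p = 0.117). Lipoxygenase A (Solyc08g014000.3) of oxylipin synthesis went from 2619 ± 577 to 7758 ± 622 CPM (SD, n = 3 each). Of 33 NAC genes, 3 rose, 3 fell and 27 were not called (the same adjusted over the list alone; camera adjusted p = 0.659). SlNOR-like1 itself is among the 3 that fell.

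**Figure D4:**
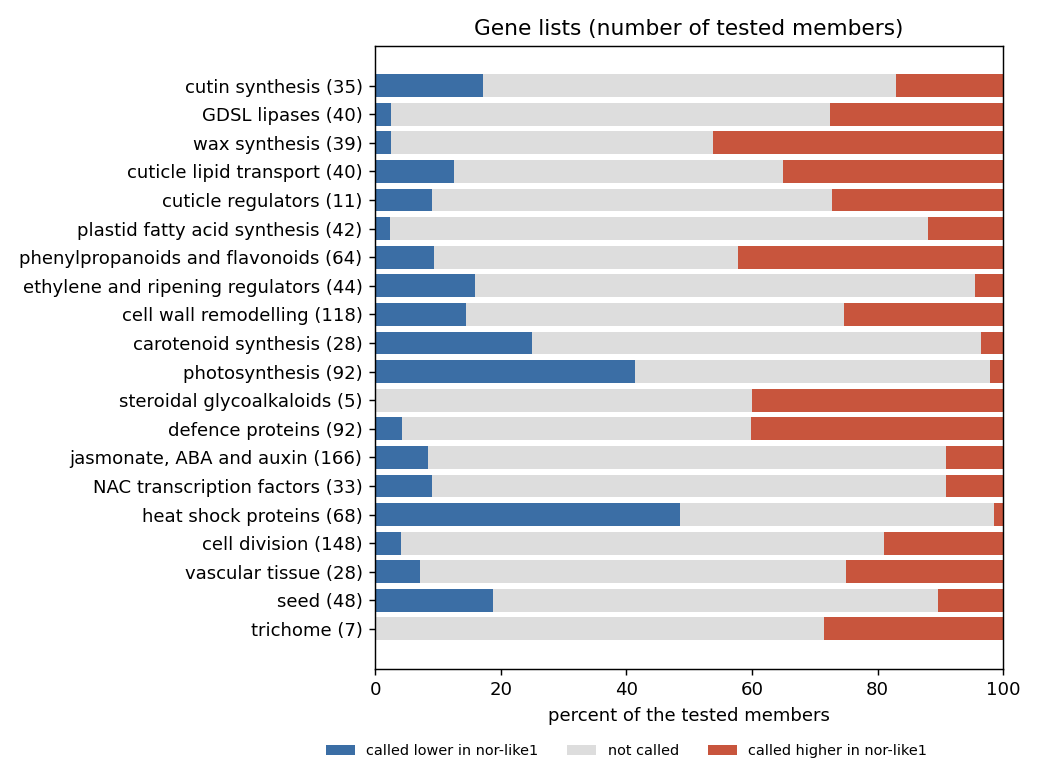
Percent of the tested members of each of the 20 gene lists called higher, lower or not called in nor-like1 against WT (bars sum to 100, number of tested members in parentheses). The heat shock (33 of 68) and photosynthesis (38 of 92) lists have the most members called lower.

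Annotation terms for phenolic metabolism were enriched among the higher genes and terms for plastid functions among the lower genes. Of 687 terms tested per direction, 24 were enriched among the higher and 22 among the lower genes (one-sided Fisher's exact test, Benjamini-Hochberg adjusted). Phenylpropanoid biosynthesis led the higher genes, with 58 of 146 tested genes where 16.6 were expected (adjusted p = 1.05e-15). Negative regulation of endopeptidase activity (18 of 27, expected 3.1, adjusted p = 3.74e-09), DNA replication initiation (12 of 14, expected 1.6, adjusted p = 6.58e-08) and cutin, suberine and wax biosynthesis (10 of 29, expected 3.3, adjusted p = 0.0304) were also enriched there. Among the lower genes, chloroplast stroma led with 65 of 186 genes (expected 21.2, adjusted p = 9.28e-15), and protein folding had 30 of 129 (expected 14.7, adjusted p = 0.00477). Fisher's test takes genes as independent, so genes that vary together can make these p-values too small. In camera with an estimated correlation, the adjusted p was 0.212 for the phenylpropanoid and photosynthesis lists and 0.234 for the heat shock list.

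The authors' deposited table calls 1066 genes higher and 437 lower, all with an absolute log2 fold change of at least 1, a limit not set on the calls made here. An adjusted p below 0.05 is given for 3893 genes in the authors' deposited table. Of the authors' deposited table's 945 higher calls among the genes tested here, 811 were called higher here too, and of its 423 lower calls 397 were called lower; no gene was called in opposite directions (0 genes). Across tested genes, which are not independent, the log2 fold changes of the authors' deposited table and of edgeR had a Pearson correlation of 0.951, and both come from the same libraries. For SlNOR-like1 the authors' deposited table gives -2.53.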

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

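The tests on thinned counts and on the shorter cutin and photosynthesis lists were chosen only after the result was seen, as were those with 1 library left out for genes outside the naming rule. Of 70 named genes called beside SlNOR-like1, 55 were called under every alternative that tested them, 15 were not called under at least 1, and 0 changed sign. They were picked in the main fit for a small adjusted p or a large change, so they do not stand for all calls. Of all 3585 calls, 31.3% and 40.8% were kept without WT replicates 2 and 1. Without nor-like1 replicates 2 and 3, 38.3% and 44.1% were kept, and with the replicate block 66.3%. The other refits kept between 79.4% and 99%. HDG11-like (Solyc06g072310.3) and the sesquiterpene synthase (Solyc12g006570.2) each lost the call in 12 of 16. NOR, which was not called, changed sign with limma on FPKM (-0.12 with pseudocount 1, -0.13 with 0.1, -0.12 without a filter), with the replicate block (-0.11) and without nor-like1 replicate 1 (-0.77, highest 0.5 without nor-like1 replicate 2). SlNOR-like1 lay between -2.8 and -2.51 with 1 library left out. With 1 library left out, called genes numbered between 1139 and 4742 (596 to 2352 higher, 543 to 2390 lower), and between 714 and 1886 at least 2-fold (438 to 1287 higher, 276 to 599 lower); fewer libraries leave less power, and why each library weighs differently was not tested. Tested against a log2 fold change of 1 (glmTreat), 250 genes passed (196 higher, 54 lower), a stricter question by construction. Other settings kept the counts within 1.5 times: DESeq2 called 4121 genes, limma 3513, no filter 3479 and thinned counts 3321, of which 3126 were among the 3585. The 2-fold calls gave 43 enriched terms among higher genes against 24.

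No gene list held with an estimated correlation in camera (0 lists against 9; 4 at an unadjusted p below 0.05, and 12 in fry): adjusted p = 0.212 for GDSL lipases, wax, cuticle lipid transport, phenylpropanoids and photosynthesis, 0.214 for defence, 0.234 for heat shock, 0.364 for glycoalkaloids and 0.395 for cell division. The cause was not tested. Values from fry answer a different question, as fry does not compare a list with the other genes. Cuticle lipid transport was lost with DESeq2 (0.0507), upper-quartile factors (0.0501) and 1 CPM in 3 libraries (0.0551), glycoalkaloids with DESeq2 (0.0533), no low-count filter (0.0761) and limma without a filter (0.0923). Called only in an alternative were plastid fatty acid synthesis (limma with pseudocount 1 and 0.1, 0.0396 and 0.0393; thinned counts 0.0383; fry 0.0111), trichome (limma, 0.0259 and 0.0354), vascular tissue (thinned counts 0.0423; fry 0.0313) and carotenoid synthesis (fry 0.0169). With 1 library left out the adjusted p ranged from 0.0377 to 0.0812 for plastid fatty acid synthesis, 0.00724 to 0.121 for cell wall remodelling, 0.0418 to 0.108 for carotenoids, 0.0104 to 0.0812 for vascular tissue, 1.77e-05 to 0.0547 for cell division and 0.0166 to 0.0701 for glycoalkaloids. Directions turned only in lists not called: ripening regulators (0.273 to 0.997 with 1 library left out, 0.855 without WT replicate 3, 0.689 without nor-like1 replicate 3, 0.902 in fry), seed (0.502 to 0.981, 0.855 without WT replicate 2, 0.902 in fry) and NAC factors (0.902 in fry). The shorter cutin list gave 0.446. Photosynthesis gave 1.03e-08 with identical entries counted once and 2.07e-10 without Solyc00g entries, and adjusted p = 0.212 with an estimated correlation in both.

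The replicate numbers did not pair the libraries: same-numbered libraries' deviations from their group means correlated at 0.222, -0.23 and 0.018 across genes. With the replicate block 2626 genes were called (1364 higher, 1262 lower), and plastid fatty acid synthesis, cell wall remodelling and vascular tissue each had an adjusted p of 0.044. WT replicate 3 correlated best with nor-like1 replicate 2 (0.324). Depth limits low genes most, as nor-like1 replicate 3 needs 0.353 CPM for 3 counts.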

Other observations

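The tests on WT replicate 3, on harvest or handling and on thinned counts were chosen only after the result was seen.

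NOR and phytoene synthase 1 varied between libraries of 1 genotype. NOR (Solyc10g006880.3) measured 199.3 CPM in nor-like1 replicate 1 and 51.85 and 53.31 CPM in the others, and 110.2, 83.99 and 74.68 CPM in WT replicates 1 to 3. The carotenoid gene phytoene synthase 1 (Solyc03g031860.3), named after its values were seen, had means of 255.2 ± 137 CPM in WT and 291.8 ± 292 CPM in nor-like1 (SD, n = 3 each), with a log2 fold change of 0.19 (SE 0.745; edgeR quasi-likelihood adjusted p = 0.872). That log2 fold change was -0.06 without WT replicate 2 and -1.04 without nor-like1 replicate 1, and lay between 0.04 and 0.71 without each of the others. At the other end, 5 genes had at most 3 counts in every WT library and at least 5 CPM in every nor-like1 library, and 1 gene, the SEC3A-like exocyst subunit (Solyc07g025170.3), the reverse. The 5 are PR1 (Solyc01g106620.2), histidine decarboxylase (Solyc08g006750.4), the tropinone reductase homolog (Solyc06g083470.5), a carbonyl reductase (Solyc06g068740.4) and a gene with no described product (Solyc06g008057.1), the last 2 named after their values were seen. The abundant Solyc09g075210.3, a LEA5 protein named after its values were seen, was the most counted gene in each WT library, and its mean was 9361 ± 792 CPM in WT and 3023 ± 977 CPM in nor-like1 (SD, n = 3 each).

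The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 3585 genes with edgeR, 1370 at least 2-fold, with 46 enriched terms, and 1 of the 10 splits gave as many; the highest of the other splits gave 0 of each. At an unadjusted p below 0.05 the real split had 6204 genes and the others between 59 and 1867. Each other split mixes both genotypes within its groups, so a difference between genotypes adds to the spread within groups. Low counts of genes in the other splits were therefore to be foreseen, and no conclusion on chance is drawn from them. For the gene lists the real split had 9 lists past the threshold in camera with the preset correlation and the highest of the others also had 9, and 3 of the 10 splits gave as many. The others had between 2 and 9 lists, though they called 0 genes. Each of them is uneven in genotype, so a genotype difference can move lists there too. The number of lists called with the preset correlation therefore does not set the real split apart.

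WT replicate 3 lay between the other WT libraries and nor-like1. A wrong label is argued against by its SlNOR-like1 level of 120.8 CPM, when nor-like1 libraries were at most 24.52 CPM. Admixture of nor-like1 RNA would move all genes by 1 share of the way to nor-like1, yet the median was 0.077 for genes at least 2-fold higher (quartiles 0.003 and 0.179) and 0.252 for genes at least 2-fold lower (-0.051 and 0.471). Both sets were called with WT replicate 3 in the WT group, which favours genes with low shares. A set of 15 genes was chosen without use of WT replicate 3. Each had at most 3 counts in each of WT replicates 1 and 2 and at least 5 CPM in every nor-like1 library. Their median share was 0.029 (quartiles 0.006 and 0.07, highest 0.935), and SlNOR-like1 had 0.012. These values argue against admixture as the whole cause, while a smaller one is not excluded. No biological explanation was tested.

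The defence list was higher, with 51 of 92 members not called, and the heat shock list lower, with 34 of 68 not called (camera adjusted p = 4.14e-10 and 1.97e-08, and adjusted p = 0.214 and 0.234 with an estimated correlation). With all libraries thinned to 8503198 counts the mean log2 change was 1.81 for defence (1.69 before) and -1.06 for heat shock (-1.06 before). Thinning keeps the expected share of each gene in its library, so similar means were to be foreseen. The low-count filter was applied anew, so the means need not cover the same genes. The values show only that both changes remain at equal counts, and no further conclusion on depth is drawn. Harvest or handling that differed between genotypes may contribute. The defence list ranged over 0.85 on the log2 scale within WT alone, but a spread within WT cannot show whether handling differed between genotypes. Such a difference cannot be told apart from the knockout, because the labels give no harvest or handling record. An effect of the knockout itself stays open too.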
